A study of Caenorhabditis elegans with 2 samples.

How the data were processed

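The data are ChIP-seq peak lists of DMD-4 in L2 larvae of C. elegans, from 2 biological replicates of 1 group, called replicate 1 and replicate 2 as in the labels. Per the labels, the worms were whole larvae of pooled sexes from a transgenic strain with a GFP-FLAG tag on DMD-4, and chromatin was sheared by sonication. Per the deposited descriptions of the files, regions were called for each replicate, and for both replicates together, on alignments to the ce10 and to the ce11 assembly with a control alignment. The same source says that the thresholded list was derived by IDR, which keeps regions whose ranks repeat between replicates, from the pooled and the per-replicate candidate lists. The aligner, the peak caller, their versions, the IDR threshold and the control's identity are not given in the sources used here.

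The signal of each region is the authors' value from the deposited lists, an enrichment that is never negative and whose scale is not given in the sources used here. It was used only to describe, rank or filter regions within a list. The deposited −log10 q-value of each region reaches a tied maximum in every IDR peak of a list, so it was not used for ranking. The summit is the deposited offset in bp within each region, in other words the position of the highest signal. Candidate lists hold weak regions on purpose, since IDR needs them. No reads or counts were used here, so depth per sample is unknown and intervals cover the counting of regions or genes only. Signal tracks, alignments and the control were not used here.

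Coordinates are 1-based in ce11, which is the same sequence as WBcel235; all region ends lay within its chromosome lengths. Genes came from Ensembl release 115. Mitochondrial genes without a symbol there took that of the RefSeq gene of the same assembly that covers at least 90% of the same span. The ce10 lists served for counts, overlaps and correlations only. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

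Bound regions are the IDR peaks of ce11 and background regions are the candidate regions of the pooled list that overlap none of them. A region belonged to a promoter when its summit lay from 1000 bp upstream to 200 bp downstream of any annotated start site of a protein-coding gene. Shares were compared by two-sided Fisher's exact tests, given as the sample odds ratio with a 95% conditional exact interval, with Benjamini-Hochberg adjustment over the 9 tests of bound against background and of stronger against weaker regions. Sequences were searched on both strands within 100 bp of the summit. For 7-mers, each IDR peak was matched to 2 background regions of like GC content and the same promoter class, and the adjustment ran over 8192 7-mers at a threshold of 0.05. Gene lists were tested among genes with any candidate region in the window, as 27 lists of which 17 had at least 5 members there; the tRNA, snoRNA and microRNA lists were set against genes of every biotype. The lists and the alternatives not named below as added were fixed before the data were examined, as were the tests, except where a test is said to be chosen later.

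Replicate overlap compared the 212 strongest regions of each replicate, with 10000 circular shifts of replicate 1 within chromosomes. Correlations took for each IDR peak the highest signal of the overlapping regions of each replicate, with 100000 permutations. Neighbouring IDR peaks can share such a region, most of all on the mitochondrial genome.

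The rule for naming was the 25 IDR peaks with the highest signal that overlap a region of each replicate's list, each by its nearest protein-coding start site and any other gene whose promoter window holds the summit; up to 6 bound members of each list by signal; and dmd-4 and unc-119. Alternatives were the ce10 lists, each replicate alone, the stronger IDR peaks, other promoter windows, other backgrounds, other summit windows and other overlap criteria. Analyses without the mitochondrial genome, of autosomes or X alone, of merged regions and of the MAB-3 core in single replicates, the location on X of stronger against weaker regions, and correlations matched on signal, were added after seeing the data.

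The tests were tested on simulated data. A 7-mer planted in 10% of 212 background windows was recovered in 18 of 20 runs and one in 5% in 1 of 20, and with none planted 0 of 20 runs made a call. Both sets of windows in these runs were drawn at random from background regions, without the matching step. The runs therefore do not cover false calls from differences in GC content or promoter class. A list of 40 genes whose members were weighted 7 times was called in 191 of 200 runs, one weighted 3 times in 66 of 200 and an unweighted one in 1 of 200. Genes were drawn singly there, so genes that share a region are not covered. For replicate overlap, 2 sets sharing 10% of 212 regions were called in 20 of 20 runs and unrelated sets in 0 of 20.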

Results

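Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map DMD-4 across the genome of Caenorhabditis elegans at the L2 larval stage. DMD-4 is a member of the DM-domain family, whose zinc-containing DNA-binding fold is shared with MAB-3 and with insect Doublesex. The worms were whole larvae of both sexes from a transgenic strain that makes DMD-4 fused to GFP and FLAG at its C terminus. There was 1 group with 2 biological replicates, drawn from separate samples of worms, and no second condition. The values were therefore compared between bound and background regions, between replicates and between chromosomes.

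In the ce11 assembly, 212 regions passed the authors' irreproducible discovery rate (IDR) threshold and are called IDR peaks here. Of these, 185 were nuclear, 46 of them on chromosome X, and 27 lay on the mitochondrial genome. Chromosome III carried 37, chromosome II 28, chromosome V 27, chromosome IV 25 and chromosome I 22. The authors' ce10 list held 218 IDR peaks, 47 of them on X and 28 on the mitochondrial genome. The list of candidate regions called on both replicates together held 11281 regions in ce11, and the 212 IDR peaks were the 212 regions of that list with the highest signal. Merging overlapping intervals left 196 regions. The per-replicate candidate lists held 17531 regions in replicate 1 and 18240 in replicate 2. Read depth is unknown, because the files hold regions and not reads, so no value here carries a counting error for reads.

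The mitochondrial genome gave the highest signals in the experiment. The signal of its 27 IDR peaks ranged from 665 to 19914, with a median of 2784, while the strongest nuclear IDR peak reached 251.6. These regions covered 12221 of 13794 bp, or 88.6%. The 25 strongest IDR peaks were all mitochondrial. The first had its summit at position 4769 of the region from 3393 to 5117, inside CYTB, which encodes cytochrome b, with a signal of 9011 in replicate 1 and 10534 in replicate 2. The second and the third had their summits at 13172 and 12455, inside ND5, a subunit of respiratory complex I, with pooled signals of 17404 and 8137. The others of the 25 had their nearest start sites at COX1, COX2 and COX3 (cytochrome oxidase subunits), ATP6 (a subunit of ATP synthase), ND1, ND3, ND4 and ND4L (complex I subunits), or again at CYTB and ND5. The candidate list held no mitochondrial region besides these 27, so mitochondrial IDR peaks had no background of their own. For several results the values without them are given as well.

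Among nuclear IDR peaks, most of the strongest lay on chromosome X and outside promoters. The 25 with the highest signal were chosen for description after the values were seen, since the 25 of the whole list were mitochondrial. The 3 strongest were an intergenic region at X:9465773-9465986 near ZK899.6 with a signal of 251.6, an intergenic region at X:11094019-11094342 near W02H3.3 with a signal of 248.0, and a region at X:2996993-2997182 in an intron of Y41G9A.17 with a signal of 235.2. Further intergenic regions lay at X:12363065-12363232 near F19H6.5 (signal 213.6), X:4209192-4209358 near F20B6.9 (200.6), X:13700640-13700989 near K02D3.1 (193.1), X:16681981-16682330 near F22H10.2 (175.4) and X:1626941-1627290 near fbxb-58 (167.0). A region at X:6296435-6296784 lay in an intron of mom-1 (signal 163.2). The summit at X:8036345-8036535 lay 4863 bp upstream of xol-1, the switch gene of sex determination and dosage compensation, with a signal of 160.1. The rest of the 16 on X were nearest to col-185, gtr-1, T27A8.7, T24D8.6, F55G7.5 and nspc-17, with signals from 118.6 for nspc-17 to 140.8 for col-185.

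The other 9 of these 25 were autosomal and all lay in promoter windows, from 1000 bp upstream to 200 bp downstream of a start site. At IV:4750011-4750155 the summit lay 151 bp upstream of Y17G9B.5 and 311 bp upstream of rpl-20, with a signal of 215.4. At III:3867483-3867642 it lay 299 bp upstream of rpl-3, with a signal of 214.1. The region at III:5679077-5679200 was shared by ska-3 and rps-12 (signal 143.5), and that at IV:654749-655098 by rpl-15 and K11H12.8 (140.3). rpl-3, rpl-15, rpl-20 and rps-12 encode cytosolic ribosomal proteins. The rest lay upstream of cdc-48.1, an AAA ATPase of protein turnover (II:10563505-10563615, signal 143.2), of H41C03.3, with ZK1248.17 nearest (II:5844649-5844998, 151.1), of egg-5 (I:4172174-4172523, 140.3), of pcn-1, the replication clamp PCNA (IV:4049542-4049891, 121.4), and of Y55F3AR.2 and the chaperonin subunit gene cct-8 (IV:1094191-1094540, 120.0). X held 16 of the 25 strongest nuclear IDR peaks and 30 of the other 160, an odds ratio of 7.70 (95% interval 2.85 to 21.5, two-sided Fisher's exact test, p = 8.17e-06); this test was chosen after the positions were seen.

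**Figure D1:**
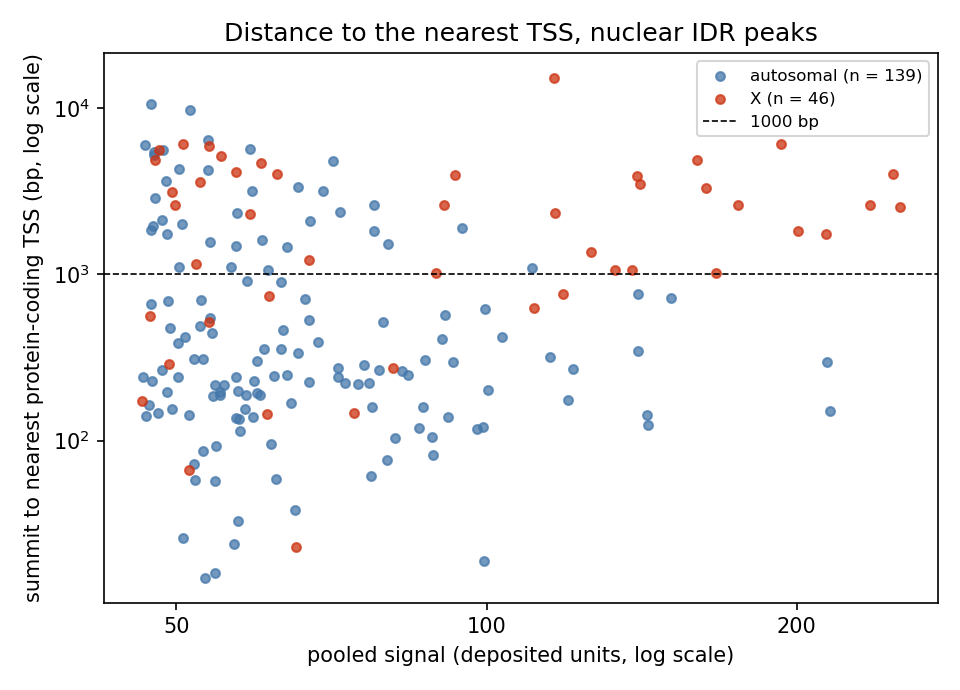
Distance in bp from the summit of each nuclear IDR peak to the nearest start site of a protein-coding gene (log scale) against its pooled signal in the authors' units (log scale). Each point is 1 region, blue for autosomal and red for the 46 X-linked regions. Most of the strongest regions on X lie above the dashed line at 1000 bp, while autosomal regions have a median distance of 284 bp.

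Autosomal IDR peaks lay in promoters and X-linked ones mostly did not. On the autosomes, 99 summits (71.2%) fell in the promoter window of a protein-coding gene and 40 did not, against a promoter share of 33.5% of 8683 autosomal background regions, an odds ratio of 4.90 (95% interval 3.35 to 7.29). On X, 12 of 46 (26.1%) did, against 25.2% of 2365 X background regions, an odds ratio of 1.05 (0.489 to 2.09, Fisher's exact p = 0.865). Autosomal and X-linked IDR peaks differed from each other in this share, with an odds ratio of 7.01 (3.13 to 16.3). The median distance from summit to nearest start site was 284 bp on the autosomes and 2447.5 bp on X (permutation test, p = 1e-05, the smallest that 100000 permutations can give). Of the 46 on X, 28 were intergenic, 5 intronic and 1 in a coding exon. Of the 40 autosomal regions outside promoters, 24 were intergenic, 13 intronic, 2 in a 3′ UTR and 1 in a 5′ UTR. Over all chromosomes, 133 of 212 summits (62.7%) fell in a promoter window against 31.8% of 11048 background regions, an odds ratio of 3.62 (2.71 to 4.85, two-sided Fisher's exact test, p = 6.21e-20, adjusted p = 5.59e-19 over 9 tests). Without the mitochondrial genome it was 111 of 185 summits (60%), an odds ratio of 3.22 (2.37 to 4.40). The split by chromosome was chosen after the data were seen, and annotated start sites in this species are often trans-splice sites downstream of the true start.

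The share of IDR peaks on X did not differ detectably from that of the background. X carried 21.7% of IDR peaks and 21.4% of background regions, an odds ratio of 1.02 (95% interval 0.715 to 1.42, Fisher's exact p = 0.933). This does not compare density by length, as the candidate list held 137 regions per Mb on X and 107 on the autosomes. Without the mitochondrial IDR peaks the shares on X were 24.9% and 21.4%, an odds ratio of 1.22 (0.848 to 1.71, Fisher's exact p = 0.278). Nor did the autosomal arms differ from the centres: 61.9% of autosomal IDR peaks and 59.4% of background regions lay outside the middle part when each chromosome was divided into 3 equal parts (odds ratio 1.11, 0.775 to 1.59, Fisher's exact p = 0.602). The adjusted p was 0.933 for X among all IDR peaks and 0.794 for the arms.

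Genes of the cytosolic ribosome were bound more often than other genes. Of 40 ribosomal protein genes with any candidate region in the promoter window, 10 had an IDR peak (25%), against 4.58% of the other 3580 genes, an odds ratio of 6.94 (95% interval 2.97 to 14.9, Fisher's exact test with Benjamini-Hochberg adjustment over 17 lists, adjusted p = 0.000104). For nuclear regions it was 7.44, and 4.563 within strata of GC content (permutation p = 0.00102). The stronger 106 IDR peaks gave 14.6 and all annotated genes as the background 16.95. By signal these were led by rpl-20, rpl-3, rps-12, rpl-15, rpl-35 and rps-20. The region of rpl-35 at III:7854539-7854888 had a signal of 103.4 and that of rps-20 at I:14469207-14469556 a signal of 97.8. The other 4 were rpl-24.2, rps-1, rpl-12 and rps-15, with signals from 50.2 for rps-15 to 91.9 for rpl-24.2. At rpl-20, rps-12, rps-20 and rps-15 another gene had the nearer start site (Y17G9B.5, ska-3, ekl-4 and F36A2.9). When each region was given only to its nearest start site, 6 of 25 ribosomal protein genes were bound (odds ratio 8.34, Fisher's exact test, adjusted p = 0.00423). All 10 regions overlapped a candidate region of each replicate, as did all 185 nuclear IDR peaks, so this does not set them apart.

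Small nucleolar RNA (snoRNA) genes were also bound more often, at 8 of 90 (8.89%) against 2.78% of other genes (odds ratio 3.41, Fisher's exact test, adjusted p = 0.0224). The members with the highest signals shared their regions with protein-coding genes: F54E7.10 and F54E7.11 that of rps-12, C06A1.9 that of cdc-48.1, and K11H12.13 and K11H12.12 that of rpl-15. The exact test counts genes that share a region, as at rps-12 and rpl-15, as independent. T27A8.8 lay beside an X-linked region with a signal of 138.5. When each region was given only to its nearest start site, 2 of 59 snoRNA genes were bound (odds ratio 1.18, Fisher's exact test, adjusted p = 1), and by nearest gene at any distance the odds ratio was 0.836. In a window from 500 bp upstream to 100 bp downstream it was 1.99 (Fisher's exact test, adjusted p = 0.464), and over all other settings the adjusted p ranged from 0.000279 to 1. Transfer RNA genes had 28 of 206 bound (13.6%, odds ratio 5.90, Fisher's exact test, adjusted p = 6.73e-11), but this rested on the mitochondrial genome: of the nuclear tRNA genes 8 of 186 were bound (odds ratio 1.79, adjusted p = 0.391).

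No other list passed the adjusted threshold. Two-sided Fisher's exact tests found 0 lists bound less often after adjustment and 1 at an unadjusted p under 0.05. That list was the chemoreceptor genes, with 1 of 140 bound (srh-16) against 4.97% of other genes (odds ratio 0.138, exact test, adjusted p = 0.0594); the adjusted p ranged from 0.00147 with all annotated genes as the background to 0.781 over the other settings. With replicate 1 left out the odds ratio was 0.301, and with replicate 2 left out it was 0.470 (exact test, adjusted p = 0.259 and 0.781). Heat shock protein genes had 2 of 7 bound, hsp-60 (signal 100.3) and hsp-90 (87.1), with an unadjusted Fisher's exact p of 0.0411 and an adjusted p of 0.140; the adjusted p ranged from 0.0391 with the stronger 106 IDR peaks to 1 by nearest gene at any distance, where 0 of 6 were bound. Translation factor genes had 2 of 16, eif-3.C and eif-3.B, with signals of 67.2 and 53.1. Proteasome and ubiquitin genes had 1 of 10 (ubq-2), homeobox genes 1 of 11 (ceh-38), neuropeptide genes 1 of 24 (the insulin-like gene ins-39), nuclear hormone receptor genes 1 of 67 (nhr-158) and microRNA genes 3 of 42 (mir-354, mir-2214 and mir-52, Fisher's exact test, adjusted p = 0.329). With the strongest regions of replicate 2 alone, 5 of the 42 microRNA genes were bound, and with those of replicate 1 alone 3 (Fisher's exact test, adjusted p = 0.0284 and 0.337). Over all other settings that adjusted p ranged from 0.0284 to 0.937. Pan-neuronal, cilium, axon guidance and adhesion, intestine, cuticle collagen and bHLH genes had none bound, of 10, 9, 10, 5, 17 and 7 members; with so few members these tests could not exclude odds ratios of 4.82 for collagens and of 8.89 for pan-neuronal genes.

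**Figure D2:**
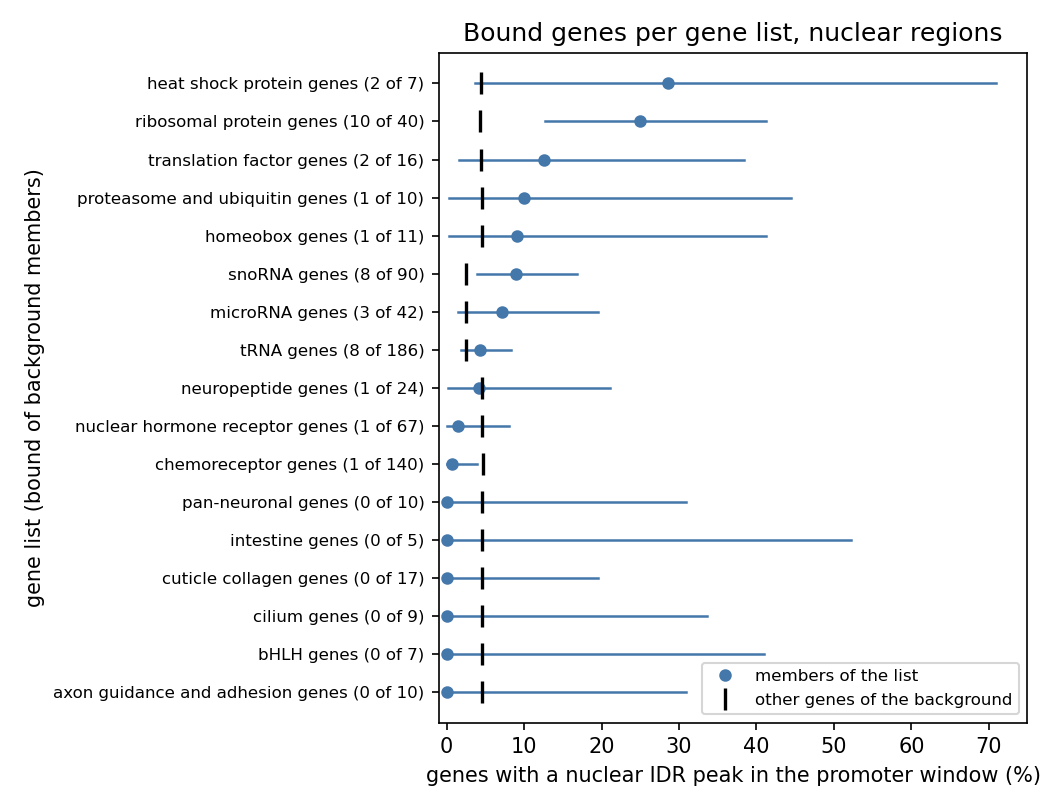
Percentage of genes with a nuclear IDR peak in the promoter window, for the 17 gene lists with at least 5 members in the background. Dots are list members with exact 95% binomial intervals, which cover counting of genes only, and vertical bars are the other genes of the background. The intervals of the ribosomal protein genes (10 of 40) and the snoRNA genes (8 of 90) lie above their bars, and that of the chemoreceptor genes (1 of 140, adjusted p = 0.116 in the exact test) lies below.

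The remaining 10 lists had fewer than 5 members in the background and were not tested. Of these, histone genes had 1 member bound of 3 (his-37, signal 88.8). DM-domain, chemosensory signalling, pharynx, body wall muscle, epidermal regulator, glia, germline, heterochronic and sex determination genes had none of 0 to 4 members bound.

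The dmd-4 gene itself (WBGene00007776, X:14857303-14861852) carried an IDR peak in an intron. It spanned X:14859048-14859397 and had a pooled signal of 91.0, with 47.8 in replicate 1 and 46.1 in replicate 2. Altogether 4 IDR peaks lay within 50 kb of dmd-4, where 0.271 would fall if the 46 on X were spread evenly by length (two-sided exact binomial test, p = 0.000162). A pair of them lay between X:14840148 and X:14841402, upstream of egrh-1, with signals of 48.1 and 60.4, and the other was in an intron of T04C10.3 at X:14813335-14813684 with a signal of 52.2. The whole candidate list held 30 regions in that span, against 14.3 by length (exact binomial p = 0.000252). Replicate 1 had 42 candidate regions there against 21.4 by length, and replicate 2 had 32 against 22.6, which did not pass the threshold (exact binomial p = 7.36e-05 and 0.0566). unc-119 (WBGene00006843, III:10902641-10908935), the selectable marker whose mutation the strain carries, had no IDR peak within 50 kb, where 0.285 would fall by length; 14 candidate regions lay there, against 12.3 by length (exact binomial p = 0.565). The span of 50 kb was chosen after the positions were seen. Both dmd-4 and unc-119 are carried by the transgene, and its copies were not told apart from the native genes here. The binomial tests also count neighbouring regions, such as the pair upstream of egrh-1, as independent.

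The DM-domain core sequence ACAWTGT, where W is A or T, was not detectably more frequent at IDR peaks. It occurred within 100 bp of the summit in 10 of 212 IDR peaks (4.72%) and in 3.32% of 11048 background regions (odds ratio 1.44, 95% interval 0.675 to 2.74, Fisher's exact p = 0.246, adjusted p = 0.737). One of the 10 was the rpl-3 promoter region. The core of the MAB-3 site, TGTTGC, occurred in 8.02% and 7.76% (odds ratio 1.04, 0.589 to 1.71, Fisher's exact p = 0.897, adjusted p = 0.933).

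**Figure D3:**
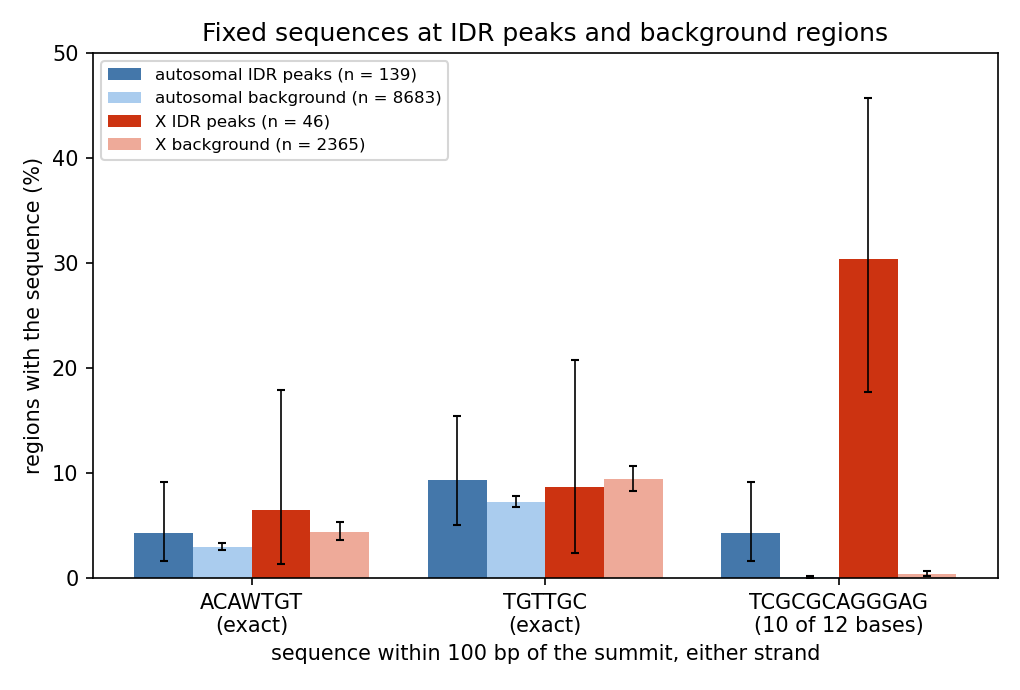
Percentage of regions with a given sequence within 100 bp of the summit on either strand, for autosomal and X-linked IDR peaks and their background regions. Bars start at 0 and error bars are exact 95% binomial intervals, which cover counting of regions only. ACAWTGT and TGTTGC differ little between IDR peaks and background, while at least 10 of the 12 bases of TCGCGCAGGGAG occur in 30.4% of X-linked IDR peaks and 0.381% of the X background. Background regions are not matched on GC content.

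A search over all 8192 7-mers, with reverse complements merged and a background matched on GC content and promoter class, gave 18 enriched 7-mers and 0 depleted ones (Fisher's exact test with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 333 and 116. By the exact test, the leading 3 were CTTGCGC, in 9.91% of IDR peaks and 0.708% of the background (adjusted p = 0.000277), CCCTGCG, in 9.43% and 0.708% (adjusted p = 0.000388), and GCAGGGA, in 9.91% and 0.943% (adjusted p = 0.000405). The top regions of a single replicate gave 5 to 7 enriched 7-mers, and the stronger 106 IDR peaks gave 7. CCCTGCG and GCAGGGA were among those of each of these 3 settings, and CTTGCGC was among none of them. CGCAAGC, whose reverse complement GCTTGCG overlaps CTTGCGC, was enriched in replicate 2 alone and in replicate 1 alone (Fisher's exact test, adjusted p = 0.0189 and 0.00682). It was not among those of the stronger 106. The unmatched background gave 248. Without the mitochondrial genome 19 were enriched, of which 12 were among the 18.

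Autosomes and X were set apart by these sequences. Tested separately, 15 7-mers were enriched at autosomal and 7 at X-linked IDR peaks, with 0 in common, and 275 and 146 passed at an unadjusted p under 0.05. CCCTGCG was present at 15 of the 46 X-linked and 5 of the autosomal IDR peaks (32.6% and 3.60%, odds ratio 12.97, Fisher's exact test adjusted over 10 comparisons, p = 3.54e-06). The opposite held for CTTGCGC, at 1 X-linked and 20 autosomal regions (2.17% and 14.4%, odds ratio 0.132, exact test, adjusted p = 0.0362), and for AGTGCGC, at 0 and 20 (adjusted p = 0.00739). For TGCGCCA, at 2 and 20, the difference did not pass the threshold (exact test, adjusted p = 0.124). These comparisons were chosen after the enriched 7-mers were seen, which favours a difference.

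The strongest regions of the replicates overlapped more than shifted regions did. Of the 212 regions of replicate 1 with the highest signal, 129 (60.8%) overlapped one of the 212 strongest of replicate 2, against a mean of 14.2% when replicate 1 was shifted around each chromosome (one-sided permutation test, p = 0.0001, the smallest that 10000 shifts can give). The shifted value came mostly from the mitochondrial genome: among the 185 strongest nuclear regions the overlap was 54.6% against 0.132% for shifted regions (permutation p = 0.0001). The share depended on how many regions were compared: it was 80.2% for the 106 strongest and 35.5% for the 848 strongest. All 212 IDR peaks overlapped a candidate region of replicate 1, and all but 1, a mitochondrial region near ND2, one of replicate 2.

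The replicates ranked X-linked IDR peaks more alike than autosomal ones. Across the 46 on X, Spearman's rho between the replicates' signals was 0.834 and Pearson's r on the log2 scale was 0.865 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give). Across those on the autosomes, rho was 0.314 (p = 0.00015) and r was 0.427 (p = 1e-05). The difference in rho of 0.519 exceeded that of permuted chromosome labels (permutation p = 0.0017). It was smaller once signal was matched in part, a test chosen after the data were seen: 46 autosomal IDR peaks paired with those on X by pooled signal had a rho of 0.608, a difference of 0.226 (labels swapped within pairs, permutation p = 0.0001, the smallest that 10000 swaps can give). The pairing matched the medians (77.8 on X and 78.3) but not the strongest regions. X held 10 of the 12 strongest nuclear IDR peaks and reached 251.6, while the paired autosomal regions reached 215.4. The wider range of signal left on X can raise rho, so this test cannot separate the remaining difference from signal. Over all 211 IDR peaks found in both replicates rho was 0.660 and r was 0.968, a value carried by the gap between mitochondrial and nuclear signals. The nuclear regions alone gave 0.495 and 0.644. Of 7 correlations computed, the largest adjusted p was 0.00015. Regions are not independent replicates, and all had passed the authors' IDR threshold and lie above the same pooled signal. Of the 212 IDR peaks, 123 were among the 212 strongest regions of both replicates.

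**Figure D4:**
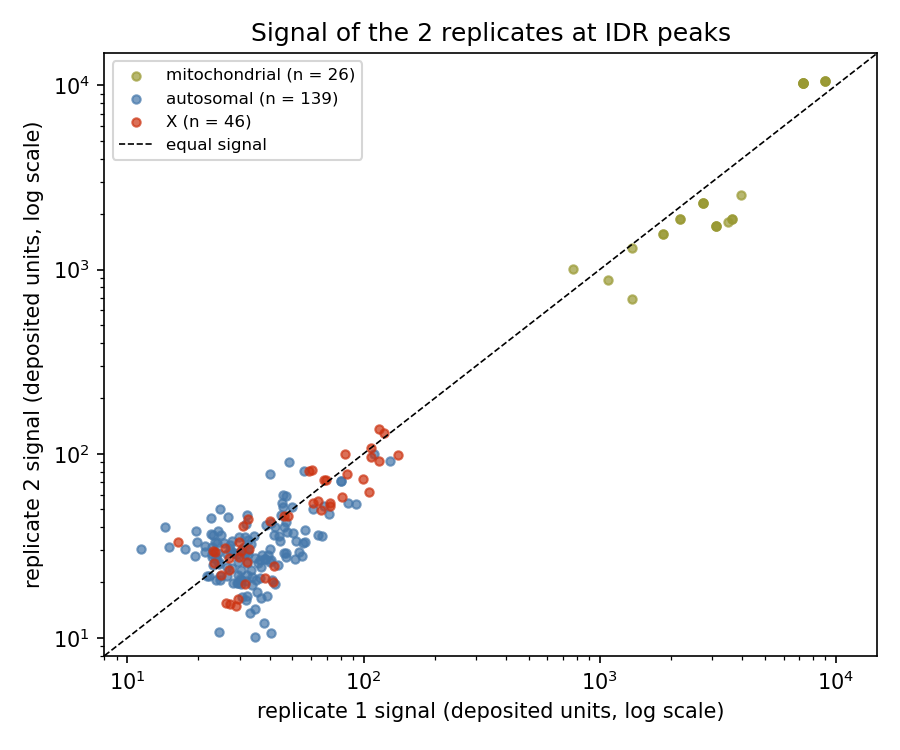
Signal of replicate 2 against that of replicate 1, in the authors' units on log scales, at 211 IDR peaks with a candidate region in both. Points are regions, blue autosomal, red X-linked and olive mitochondrial, and the dashed line marks equal signal. Mitochondrial regions form a separate cloud at the top, and X-linked regions follow the line more closely (rho 0.834) than autosomal regions (0.314).

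Regions in the promoter window of a gene from any of the lists made up 35 of the 106 stronger and 15 of the 106 weaker IDR peaks (odds ratio 2.99, 95% interval 1.45 to 6.35, Fisher's exact p = 0.00193, adjusted p = 0.00867). Without the mitochondrial genome, whose tRNA genes belong to a list, these were 19 and 12 of 92 (odds ratio 1.74, Fisher's exact p = 0.237). Among autosomal regions, where rpl-20 and rpl-3 lead, they were 18 and 7 of 69 (odds ratio 3.13, Fisher's exact p = 0.0257). Promoter position (65.1% and 60.4%, p = 0.570), ACAWTGT (6.60% and 2.83%, p = 0.332) and location on X (23.6% and 19.8%, p = 0.617) did not pass the threshold of the exact test. All mitochondrial regions fall among the stronger, and without them the shares on X were 30.4% and 19.6% (odds ratio 1.80, Fisher's exact p = 0.125). Location on X was added to these tests after the data were seen.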

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

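Settings restricted to nuclear, autosomal or X-linked regions, merged regions, the single-replicate runs of the MAB-3 core and location on X in stronger against weaker IDR peaks were chosen after seeing the data; the others were planned. Of 97 values recomputed under another setting, 84 kept their direction and their side of the threshold, or a count of similar size. Another 5 were no longer past the threshold, 3 reversed and 5 counts moved further. The 84 include results that were never past the threshold, such as the shares on X and on the arms. The promoter share kept its direction and its side of the threshold, with odds ratios from 2.48 to 4.90, except on X alone, where it was 1.05. The odds ratio of the ribosomal protein genes stayed past the threshold in the settings compared here, from 6.75 to 16.95, and was 4.563 within strata of GC content. The DM-domain core changed direction within 250 bp of the summit (odds ratio 0.976) and ranged from 0.986 to 1.45 with 1 replicate left out. Among these settings its odds ratio against background was highest for the stronger 106 IDR peaks, at 2.06 (Fisher's exact p = 0.0917). Outside these settings, autosomal IDR peaks away from promoters gave 2.61 (3 of 40, Fisher's exact p = 0.121). The DM-domain core was never past the threshold, and the cause of these changes was not tested. CTTGCGC was not among the enriched 7-mers of either replicate alone or of the stronger 106 IDR peaks, while the overlapping CGCAAGC was among those of each replicate alone. The number of enriched 7-mers was 5 to 7 with 1 replicate left out, 7 for the stronger 106 IDR peaks, 7 for X alone and 248 with an unmatched background, against 18; fewer regions were tested in the stronger and X settings, and the cause was not tested for the rest. The snoRNA odds ratio was 0.836 by nearest gene at any distance, 1.18 by nearest start site only and 1.99 in the window from 500 bp upstream to 100 bp downstream; regions shared with a protein-coding gene leave the list when only the nearest start site counts. Without the mitochondrial genome, the odds ratio of list genes in stronger against weaker IDR peaks was 1.74 and that of tRNA genes 1.79. A stricter IDR was planned and not run, since the lists hold no IDR value. No paired analysis was possible because there is 1 group. Depth is unknown, so its limit on the number of IDR peaks cannot be given.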

Other observations

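The tests of the 12-base sequence at 9 and 11 matching bases and outside promoters, of mitochondrial coverage, of the share of regions with a DM-domain core and of autosomal against X-linked regions were chosen after the result was seen, and the X-linked, mitochondrial and promoter patterns were themselves noticed in the positions of the IDR peaks.

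Further autosomal promoter regions, named here after their values were seen and not as a tested group, lay at cox-5A, a cytochrome oxidase subunit (III:12904998-12905347, signal 115.2), ints-4, an Integrator subunit (I:13663158-13663507, 99.5), ntl-11, of the CCR4-NOT complex (IV:15471441-15471790, 99.3), apb-1, an adaptor subunit of vesicle coats (III:2597157-2597506, 92.8), and spd-2, a centrosome gene (I:8969982-8970331, 80.1). On X, a promoter region lay at puf-9, an RNA-binding protein gene (X:5841144-5841493, signal 81.2).

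Some X-linked IDR peaks far from promoters may mark recruitment sites of the dosage compensation complex, whose known 12-base motif is TCGCGCAGGGAG. At least 10 of its 12 bases were found within 100 bp of the summit in 14 of 46 X-linked IDR peaks and 9 of 2365 X background regions, an odds ratio of 114.5 (95% interval 42.04 to 318.7, Fisher's exact p = 7.07e-20), including 11 of the 34 outside promoters. Autosomal IDR peaks also held it more often than their background, in 6 regions (4.32% against 0.138%, odds ratio 32.6), less often than those on X (odds ratio 9.70 for X against autosomes, Fisher's exact test, adjusted p = 1.9e-05); at least 9 bases occurred in 41.3% of X-linked and 19.4% of autosomal IDR peaks (odds ratio 2.92, adjusted p = 0.00756), and at least 11 in 11 and 0 regions. The background of the 12-base sequence was not matched on GC content. Mean GC content was 38.4% at X-linked IDR peaks and 31.4% in their background, and 38.8% and 30.3% on the autosomes. The odds ratios of 114.5 and 32.6 are therefore not adjusted for base composition. The X-enriched 7-mers CCCTGCG, GCAGGGA, TCGCGCA and CCTGCGC are stretches of the 12-base sequence or its reverse complement. Their background was matched on GC content and promoter class. CCCTGCG occurred in 32.6% of X-linked IDR peaks and 1.09% of that background, GCAGGGA in 32.6% and 2.17%, and TCGCGCA in 23.9% and 0%. The excess of these stretches on X remained with GC content matched, though the search had picked them. A higher amount of DNA or reads from X as a whole stays open: the median signal of background regions on X was 1.005 times that on the autosomes (bootstrap 95% interval 0.995 to 1.02), but the candidate list begins at a signal of 13.035, which holds that median near its floor, and X carried 137 candidate regions per Mb against 107 on the autosomes. Most of these summits lacked an exact ACAWTGT, as 3 of 46 had it (6.52%, exact 95% interval 1.37% to 17.9%). Inexact matches to it were not searched, so a DM-domain site of another form is not excluded. An excess of ACAWTGT in a few (odds ratio 1.502, 0.293 to 4.81) and whether DMD-4 binds at the regions without it stay open.

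For the mitochondrial IDR peaks, read density over the whole mitochondrial genome and separate sites cannot be told apart. They cover 88.6% of it, which was visible before the test was chosen and so decides nothing, and their signals range from 665 to 19914. No biological explanation was tested, since the design has 1 group.

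For the autosomal promoter regions, among them those of ribosomal protein genes, base composition as the whole cause of the ribosomal excess is argued against. Within 10 strata of GC content its odds ratio was 4.563, with 10 members bound where 3.39 would be expected (permutation p = 0.00102), against 7.44 without strata for nuclear regions, so GC content could account for part of the excess. Most of the summits in autosomal promoters lacked an exact ACAWTGT, as 3 of 99 had it (3.03%, exact 95% interval 0.629% to 8.60%). Inexact matches were not searched here either, and an excess of ACAWTGT in a few stays open (odds ratio 1.003, 0.199 to 3.12). Open chromatin or high transcription at these promoters, which could raise signal for many proteins, was not tested.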
